A study of Homo sapiens with 12 samples.

How the data were processed

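Total RNA from HEK293T cells, a human embryonic kidney line that is easily transfected, was sequenced in 12 libraries. The labels place them in 4 groups of 3 replicates, formed by 2 aptamer conditions and 2 media. Cells were transfected with 1.5 µg of plasmid encoding either the individual aptamers T1 and bc339, the control of the series, or the dual-specificity aptamer 3JB8F+12. An aptamer is a folded nucleic acid selected to bind a protein. All groups received 50 µM Ac5S, an inhibitor of the O-GlcNAc transferase OGT, from 4 h after transfection. At 20 h the medium was replaced by fresh DMEM (Wnt-) or by DMEM with 50% by volume of Wnt3A-conditioned medium (Wnt+). Cells were lysed in TRIzol at 24 h, 4 h later. For all groups the labels also list 1 g/L glucose and fresh medium at 6 h. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No group received conditioned medium without Wnt3A.

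The deposited count table holds whole-number read counts per Ensembl gene, 1 column per library, with no normalization by the authors. Per the submitters' processing notes, the pipeline used Trim Galore, HISAT2, featureCounts and DESeq2 with genome build GRCh38.p13. Versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Counts of overlapping or antisense genes, and of near-identical copies such as HSPA1A with HSPA1B or SLC2A3 with SLC2A14, are therefore uncertain in how reads were divided. The authors also deposited a DESeq2 table for each medium comparing the aptamers. Per the file headers these hold a mean normalised signal (count divided by size factors), a log2 fold change with its standard error, a test score (the Wald statistic), and a p-value with its adjusted value. The mean signal was the same in both tables for every gene, so the authors' size factors came from all libraries together.

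The count table lists 60683 genes, of which 28813 had 0 counts in all libraries. Symbols came from a reference name table and were found for 42013 genes. Coordinates are whole gene spans on GRCh38 from GENCODE release 29. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 17478 genes, 15665 of them with a symbol, holding 99.9% of all counts. Counts were scaled by the trimmed mean of M values (TMM), and the 12 libraries were fitted together with 1 mean per group and 8 residual degrees of freedom. Each contrast was tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Levels are CPM, counts scaled to the effective library size, fold changes are on the log2 scale with a prior count of 0.125, and intervals are 95% confidence intervals.

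Sequencing depth ranged from 19575657 to 25704332 counts per library. At this depth and replication the median standard error of a log2 fold change was 0.074 and the common biological coefficient of variation was 6.91%. The procedure was tested on simulated counts with the real gene means and library sizes. The 200 changed genes were drawn from those with a mean of at least 1 CPM, so recovery below that level was not tested. For the aptamer effect in Wnt+, edgeR recovered 72% of genes changed 1.5-fold and 92% of genes changed 2-fold. For the Wnt response with the individual aptamers it recovered 72.5% and 93%, and for the difference between the effects 58.5% and 84%. Unchanged genes made up 4.17% to 9.94% of its calls. Simulated genes were independent of each other, which real genes are not. All 200 genes were changed at once, which eases the adjusted threshold for each of them. Recovery in a contrast with few changed genes would be lower and was not tested.

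Gene lists, 33 of them with 717 symbols, were tested with camera in limma 3.58.1 on log2 CPM with voom weights and a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 5 measured members. The metallothionein list had 4 and was not tested. The same test with an estimated correlation, and the rotation test fry, were run beside it. A raise of 1.1-fold simulated in the Wnt target list gave an adjusted p = 1.11e-07, and without the raise 0.987, with 0 other lists passing in either. Genes in this simulation were independent of each other, so it could not test the preset correlation for genes that move together. The lists covered Wnt targets, Wnt pathway components, the O-GlcNAc and hexosamine pathway, Polycomb repressive complex 2, stress and immune responses, growth-factor responses, metabolism, the cell cycle, ribosomes, mitochondria, histones, abundant non-coding RNAs, splicing factors, lysosomes, and markers of fibroblasts, epithelia, neurons and leukocytes.

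The groups, contrasts, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. Named genes were CTNNB1, OGT, OGA and AXIN2 in every comparison. To these were added up to 6 genes with the highest and up to 6 with the lowest log2 fold changes past the threshold, with a symbol, at least 1 CPM in the higher group and replicates that did not overlap. Up to 3 members with the smallest p were added from each list that passed or had at least 3 called members. The alternatives were DESeq2 1.42.0, limma voom, relative log expression (RLE) size factors, library size alone, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, only the 6 libraries compared, stricter thresholds, and leaving out each library. The mean aptamer effect over both media, removal of per-library trends on transcript length, gene span and GC content, and leaving out pairs of libraries were added after seeing the data. Replicate pairs of a group differed by 2.77 to 18.2 in chi-square per gene, far above sampling noise, so none were counted as 1 sample.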

Results

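RNA was measured in 12 libraries of HEK293T cells, 3 in each of 4 groups, all treated with the OGT inhibitor Ac5S. OGT is the enzyme that attaches single N-acetylglucosamine residues (O-GlcNAc) to nuclear and cytosolic proteins, and beta-catenin is the transcriptional effector of Wnt signalling. The series describes the dual-specificity aptamer as raising O-GlcNAc on beta-catenin while OGT is inhibited, so the comparisons asked how the transcriptome responded to this aptamer and to Wnt3A-conditioned medium. Depth ranged from 20346575 to 22959099 counts per library with the individual aptamers in Wnt-, from 19575657 to 25167389 with the dual aptamer in Wnt-, from 21145288 to 22418369 with the individual aptamers in Wnt+, and from 21993429 to 25704332 with the dual aptamer in Wnt+. TMM factors lay between 0.979 and 1.02, and mitochondrially encoded genes held 4.38% to 5.06% of counts.

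CTNNB1, which encodes beta-catenin (chromosome 3, 41194741 to 41260096), was at 481 ± 14.9 CPM with the individual aptamers and 502 ± 12.7 CPM with the dual aptamer in Wnt-, and at 460 ± 4.02 and 483 ± 1.94 CPM in Wnt+ (SD, n = 3). OGT itself (chromosome X, 71533083 to 71575897) was at 255 ± 4.21, 244 ± 17.9, 225 ± 6.83 and 213 ± 18.4 CPM in the same order. OGA, the enzyme that removes O-GlcNAc (chromosome 10, 101784443 to 101818465), was at 115 ± 2.25, 110 ± 6.01, 105 ± 5.68 and 100.1 ± 4.72 CPM. None of these 3 genes passed edgeR's test in any contrast between groups with all 12 libraries. OGT was called lower in the Wnt response with the dual aptamer (-0.20, adjusted p = 0.138) without dual-aptamer Wnt- replicate 2 (-0.25, adjusted p = 0.0494), without dual-aptamer Wnt+ replicate 2 (-0.27, 0.0217) and without both (-0.32, 5.59e-04). With the individual aptamers OGT (-0.18, adjusted p = 0.141) was called without both (-0.17, 0.0192) and in a fit of the 6 libraries compared (-0.19, 0.019), but in no other of 23 alternatives, and was -0.07 (0.372) with trends on length, span and GC removed. OGA was called lower with the dual aptamer without both libraries (-0.22, 0.0144).

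**Figure D1:**
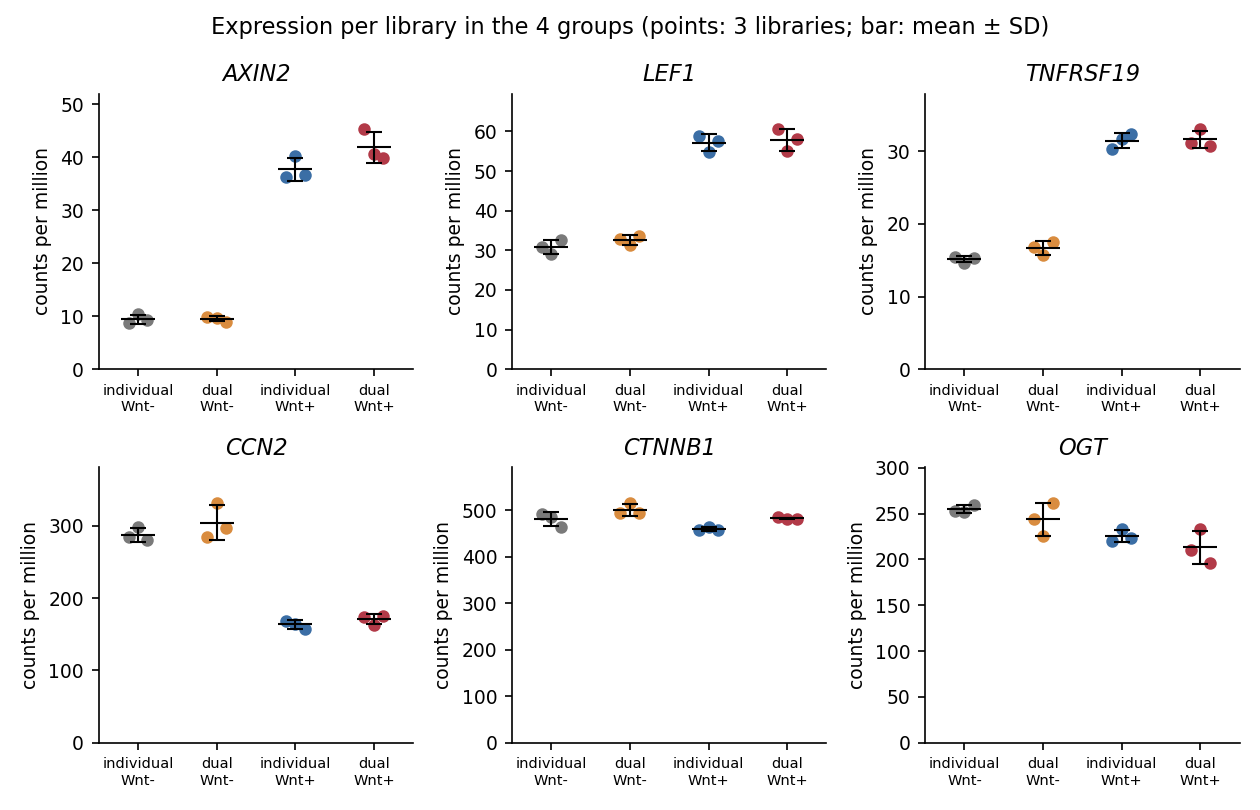
CPM (library-scaled counts) of AXIN2, LEF1, TNFRSF19, CCN2, CTNNB1 and OGT in each library (points) of the 4 groups, with the mean and SD of 3 libraries (bars). AXIN2 lies between 8.64 and 10.4 in the Wnt- libraries and between 36.3 and 45.2 in the Wnt+ libraries with either aptamer.

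With the individual aptamers, 4 h of Wnt3A-conditioned medium raised the feedback inhibitor AXIN2 (ENSG00000168646, chromosome 17, 65528563 to 65561647) from 9.44 ± 0.875 to 37.7 ± 2.17 CPM (SD, n = 3). This was a 3.99-fold change (95% interval of its log2 value 1.82 to 2.18, adjusted p = 5.3e-10). The secreted Wnt antagonist DKK1 (chromosome 10, 52314296 to 52318042) rose by 1.90 (SE 0.16, adjusted p = 2.39e-06), from 1.6 to 5.99 CPM, and the LIM-domain transcription regulator LMO2 rose by 1.75 (SE 0.16). SLC2A3, a glucose transporter at 261 ± 6.38 CPM (chromosome 12, 7919230 to 7936275), rose to 674 ± 6.51 CPM, a log2 change of 1.37 (SE 0.05, adjusted p = 1.5e-10). The inducible chaperone genes HSPA1A and HSPA1B (chromosome 6, 31815464 to 31817946 and 31827735 to 31830255) fell by 1.83 (SE 0.13) and by 1.38 (SE 0.08) on the log2 scale.

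In all, edgeR's quasi-likelihood test called 761 of 17478 genes, 448 higher and 313 lower in Wnt+, with a median absolute log2 fold change of 0.38. At least 2-fold changes numbered 47 higher and 5 lower. Scaling by library size alone gave 550 higher and 183 lower, and DESeq2 gave 461 higher and 536 lower. The count rested on single libraries: it was 243, 316 and 451 without individual-aptamer Wnt- replicates 1, 2 and 3, and 276 and 262 without individual-aptamer Wnt+ replicates 1 and 3. It lay within 1.5 times the count without any of the other 7 libraries, up to 1140 without dual-aptamer Wnt+ replicate 2. Of 47 named genes past the threshold, 26 kept their call in each of the 12 refits without 1 library, 21 lost it in at least 1, and none of the 47 changed sign. KRTAP19-5 (2.58), IGFL4 (1.99) and the sphingosine phosphate receptor gene S1PR1 (1.61) completed the 6 largest increases, from means of 0.322, 0.304 and 0.686 CPM, and each kept its call. Among the lowest, MAFK, a small Maf transcription factor gene, kept its call (-0.82, adjusted p = 4.13e-04), while TSSK5P (-0.95), EPPK1 (-0.87) and LPAL2 (-0.85) lost theirs in 5, 7 and 2 refits. For TSSK5P these were without individual-aptamer Wnt- replicates 1 and 3 (adjusted p 0.169 and 0.0743) and Wnt+ replicates 1, 2 and 3 (0.101, 0.0643 and 0.133). LPAL2 lost its call without Wnt- replicate 1 (0.0718) and Wnt+ replicate 3 (0.0555) of the same aptamers. EPPK1 lost it without individual-aptamer Wnt- replicates 1 to 3 (0.117, 0.11, 0.126), individual-aptamer Wnt+ replicates 1 and 3 (0.171, 0.201) and dual-aptamer Wnt- replicates 1 and 3 (0.0683, 0.0529), and also with DESeq2 (0.092), library size alone (0.065), the filter of 1 CPM (0.0512) and the replicate block (0.0599).

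Wnt target genes rose together with the individual aptamers. Of 25 measured members 13 rose, 1 fell and 11 did not pass, and 17 rose and 1 fell when adjusted over the list alone (camera adjusted p = 6.54e-13, median log2 fold change 0.44). With an estimated correlation the list's adjusted p = 0.00426. TNFRSF19 rose from 15.1 ± 0.413 to 31.4 ± 1.05 CPM (1.06, adjusted p = 9.45e-08), and LEF1, a DNA-binding partner of beta-catenin, from 30.8 ± 1.81 to 57.1 ± 2.11 CPM (0.89, adjusted p = 3.43e-07; SD, n = 3). The member that fell was JUN (-0.32, adjusted p = 0.0144), an immediate-early transcription factor gene chosen after its values were seen. Among 32 pathway components 3 rose, 2 fell and 27 did not pass, and the list did not pass (adjusted p = 0.843). Its median (-0.02) and its test pointed down while its mean (0.04) was positive. The receptor gene FZD10 rose by 1.15 and TCF7L1 by 0.51, and both kept their calls in the 12 refits. FZD2 rose by 0.44 but lost its call without individual-aptamer Wnt- replicate 2 or 3 (edgeR adjusted p up to 0.0715).

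The YAP, TGF-beta and BMP, ribosome biogenesis, heat shock and immediate-early lists fell in the same comparison. The YAP, TGF-beta and BMP list had 0 higher and 8 lower of 26 (3 and 14 adjusted over the list alone; adjusted p = 1.78e-07; 0.00426 with an estimated correlation). Its matricellular genes CCN2 and CCN1 fell by 0.81 (SE 0.06, from 288 ± 9.46 to 164 ± 5.94 CPM, n = 3) and by 0.49 (SE 0.06), and PMEPA1 fell by 0.58. Ribosome biogenesis genes had 0 higher and 9 lower of 21 (17 lower adjusted over the list alone; adjusted p = 5.14e-12; adjusted p = 0.0342 with an estimated correlation), with RRP12 at -0.33. Heat shock genes had 7 lower and 0 higher of 17 (8 lower adjusted over the list alone; adjusted p = 1.11e-10, but adjusted p = 0.109 with an estimated correlation), and HSPA8, the constitutive cytosolic chaperone, fell by 0.63 (SE 0.07). Immediate-early genes had 12 lower and 1 higher (KLF6, chosen after its values were seen) of 26, the same numbers adjusted over the list alone (adjusted p = 6.39e-09, but adjusted p = 0.0746 with an estimated correlation). Among them EGR1 fell by 0.62 (SE 0.09), the serum response factor gene SRF by 0.50 (SE 0.07) and ARC by 0.76 (SE 0.12).

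A further 8 lists passed with the preset correlation alone. Lower lists were splicing factors (3 of 17 fell, 9 adjusted over the list alone; median -0.17, adjusted p = 1.06e-07), p53 targets (3 of 18 fell, 4 over the list alone; -0.14, 1.89e-04), NF-kappaB targets (2 of 16 fell, 3 over the list alone; -0.22, 0.00377), E2F and DNA replication genes (1 of 26 fell, E2F1, and 1 over the list alone; -0.07, 0.00326) and the O-GlcNAc and hexosamine pathway (1 of 11 fell, NAGK, and 1 over the list alone; -0.11, 0.0169). With an estimated correlation their adjusted p were 0.0867, 0.0867, 0.131, 0.461 and 0.117. With trends on length, span and GC removed, the O-GlcNAc list did not pass either (median -0.07, adjusted p = 0.261). Its median was also -0.07 without individual-aptamer Wnt+ replicate 2 (0.0279). Removing these trends took the median of splicing factors from -0.17 to -0.06 (0.0121) and of E2F genes from -0.07 to -0.05 (0.00531), and library size alone took the latter to -0.04 (0.0129). NAGK, the N-acetylglucosamine kinase gene, fell by 0.25 (adjusted p = 0.0317) and lost the call without any of the 6 individual-aptamer libraries, with values of 0.0614 to 0.14. NAGK also lost it with library size alone (0.0538), the replicate block (0.0563) and trends on length, span and GC removed (-0.13, 0.195). E2F1 (-0.23) lost it without individual-aptamer Wnt- replicate 1, 2 or 3 (0.167, 0.0775, 0.0544) or Wnt+ replicate 1 or 3 (0.1, 0.147). Of the 3 splicing factors, TRA2B (0.0532), SRSF5 (0.113) and CLK2 (0.177) all lost their calls without individual-aptamer Wnt- replicate 1. With trends on length, span and GC removed TRA2B changed from -0.26 to -0.11 and lost its call (0.137). CLK2 lost its call with library size alone (0.067) and the replicate block (0.0579), and E2F1 with library size alone (0.0543). Without other single libraries SRSF5 lost its call for individual-aptamer Wnt- replicate 2 (0.0581) and Wnt+ replicates 1, 2 and 3 (0.0605, 0.0641, 0.0589), and CLK2 in 7 more refits (0.0508 to 0.202). The NF-kappaB genes NFKB1 and NFKB2 both lost theirs without individual-aptamer Wnt- replicate 1 (0.0547 and 0.0602) or Wnt+ replicate 1 (0.0993 and 0.0537) or 3 (0.0947 and 0.0589), and NFKB1 also without Wnt- replicate 2 (0.113). Among p53 targets, the apoptosis gene BBC3 fell by 0.43 and kept its call in the 12 refits. AEN lost its call without individual-aptamer Wnt- replicate 1 (0.0601) or Wnt+ replicate 1 (0.0625) or 3 (0.0522), and BTG2 without Wnt- replicates 1 and 2 (0.114, 0.0934) or Wnt+ replicates 1, 2 and 3 (0.112, 0.0506, 0.0623).

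Lists that were higher were epithelial markers (1 of 9 rose, 3 adjusted over the list alone; median 0.37, adjusted p = 0.00467; adjusted p = 0.0746 with an estimated correlation), ribosomal proteins (0 of 46 called, 0 over the list alone; 0.12, 2.33e-05) and oxidative phosphorylation genes (0 of 29 called, 0 over the list alone; 0.11, 0.00377). KRT19 rose by 0.39 (SE 0.07, adjusted p = 0.00623). For ribosomal proteins and oxidative phosphorylation the adjusted p = 0.709 with an estimated correlation. The oxidative phosphorylation call was lost without individual-aptamer Wnt- replicate 3 (median 0.05, adjusted p = 0.345), and its median was 0.17 without Wnt- replicate 2 and 0.07 without Wnt+ replicate 3 of these aptamers. The ribosomal protein median was 0.06 without individual-aptamer Wnt- replicate 3.

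The 19 lists that did not pass, Wnt components included, held 25 called members. Hypoxia targets (adjusted p = 0.683) had 2 higher and 2 lower of 20, or 3 and 2 adjusted over the list alone: the hormone gene STC1 rose by 1.41 (SE 0.15) and the HIF prolyl hydroxylase gene EGLN3 by 0.64, or by 0.41 (0.0229) with trends on length, span and GC removed. Glycolysis genes (0.639) had 2 higher, SLC2A3 among them, and 1 lower of 21, and cholesterol synthesis genes (0.155) had 0 higher and 3 lower of 22. All 3 of the latter, HMGCS1, SQLE and IDI1, lost their calls without individual-aptamer Wnt- replicate 1 (0.058, 0.194, 0.152) or Wnt+ replicate 1 (0.0641, 0.134, 0.151), and SQLE and IDI1 in 5 and 7 further refits (up to 0.107 and 0.119). Counting the other settings too, the SQLE and IDI1 calls held in 14 and 10 of 23 alternatives. The glycolysis gene ENO2 lost its call without any of the 6 individual-aptamer libraries (0.0636 to 0.0948), and HK2 without Wnt- replicate 1 (0.121) or 2 (0.0526) or Wnt+ replicate 3 (0.119) of these. The hypoxia target NDRG1 lost its call without individual-aptamer Wnt- replicates 1 and 2 (0.0813, 0.0771) or Wnt+ replicates 1 and 3 (0.0693, 0.0651), and with the length trend (-0.18, 0.0558) or trends on length, span and GC removed (-0.13, 0.165). Adjusted p values of the remaining lists were 0.0974 for endoplasmic reticulum chaperones, 0.176 for mitotic genes, 0.217 for NRF2 targets, 0.273 for neuronal markers, 0.302 for leukocyte markers and for ATF4 targets, 0.306 for Polycomb repressive complex 2, 0.433 for abundant non-coding RNAs, 0.639 for interferon-stimulated genes, 0.694 for fatty acid synthesis, 0.760 for TXNIP and ARRDC genes, 0.843 for mitochondrially encoded genes, histones and fibroblast markers, and 0.872 for autophagy and lysosome genes. The median, mean and test did not share a sign for the mitotic, TXNIP and ARRDC, and mitochondrially encoded lists.

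The dual-specificity aptamer gave a response to the same medium with many of the same leading genes. AXIN2 rose from 9.52 ± 0.491 to 41.8 ± 2.97 CPM (SD, n = 3), a log2 fold change of 2.14 (SE 0.08, adjusted p = 1.57e-10). LMO2 rose by 1.86 (SE 0.16), STC1 by 1.81 (SE 0.16), DKK1 by 1.45 (SE 0.15), S1PR1 by 1.44 (SE 0.22), KRTAP19-5 by 2.24 (SE 0.25) and SLC2A3 by 1.34 (SE 0.05, from 275 ± 11.5 to 698 ± 10.2 CPM, n = 3). HSPA1A and HSPA1B fell by 1.65 (SE 0.13) and by 1.34 (SE 0.08), and CCN2 fell by 0.83 (SE 0.06, adjusted p = 6.38e-07). The chemokine gene CXCL8 fell by 0.81 (adjusted p = 0.0123), a call lost without dual-aptamer Wnt- replicate 3 (0.0636) or Wnt+ replicate 1 (0.0776).

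Here edgeR called 476 of 17478 genes, 342 higher and 134 lower, with 35 higher and 4 lower by at least 2-fold. The count fell to 174 and 219 without dual-aptamer Wnt- replicates 1 and 3 and to 162 and 206 without dual-aptamer Wnt+ replicates 1 and 3, and it was 1313 without dual-aptamer Wnt+ replicate 2. The count of genes called in each of the 12 refits without 1 library was 132 (105 higher, 27 lower), and 184 (138 higher, 46 lower) with the individual aptamers. Of 33 named genes past the threshold, 19 kept the call in every refit and 14 did not. CCL20 (-0.96, 1.78 ± 0.174 to 0.916 ± 0.28 CPM) and ANKRD37 (-0.79, 1.73 ± 0.19 to 0.996 ± 0.0253 CPM) had low counts (SD, n = 3). CCL20 lost its call without dual-aptamer Wnt- replicates 1 and 3 (adjusted p 0.131 and 0.127), dual-aptamer Wnt+ replicates 2 and 3 (0.0667 and 0.135), individual-aptamer Wnt- replicates 1 and 2 (0.0511 and 0.0521) and individual-aptamer Wnt+ replicate 3 (0.0547). ANKRD37 kept its call only without individual-aptamer Wnt- replicate 1 or dual-aptamer Wnt- replicate 2, and its adjusted p in the other 10 refits lay between 0.0607 and 0.182.

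Wnt targets had 14 higher and 1 lower (JUN, -0.29, chosen after its values were seen) of 25, or 16 and 2 adjusted over the list alone (adjusted p = 1.36e-14, median 0.43; adjusted p = 0.00278 with an estimated correlation). TNFRSF19 rose by 0.92 (SE 0.07) and LEF1 by 0.83 (SE 0.06). The YAP, TGF-beta and BMP list had 8 lower and 1 higher (TGFB1I1, chosen after its values were seen) of 26, or 12 and 1 adjusted over the list alone (adjusted p = 4.38e-08; 0.00278 with an estimated correlation), and the BMP target ID1 fell by 0.76 (SE 0.09, from 27.6 ± 3.72 to 16.4 ± 1.44 CPM, n = 3).

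A further 6 lists were lower and 3 higher at the preset correlation. Heat shock genes had 7 lower of 17 (7 over the list alone; adjusted p = 1.26e-09), with HSPA8 falling by 0.61, and immediate-early genes 8 lower and 1 higher of 26 (10 and 1 over the list alone; 1.65e-06), with EGR1 at -0.63, SRF at -0.43 and the phosphatase gene DUSP5 at -0.45, all 3 past the threshold. Ribosome biogenesis had 3 lower of 21 (9 over the list alone; 6.81e-08), splicing factors 2 of 17 (6; 8.84e-06), NF-kappaB targets 3 of 16 (7; 5.37e-04), and p53 targets 1 of 18 (3; 0.0223). With an estimated correlation these 6 gave adjusted p of 0.142, 0.118, 0.0977, 0.142, 0.118 and 0.292. All 3 called ribosome biogenesis genes, RRP12, WDR43 and MYBBP1A, lost their calls without dual-aptamer Wnt- replicate 1 (0.0877, 0.129, 0.131), dual-aptamer Wnt+ replicate 1 (0.0539, 0.16, 0.195) or dual-aptamer Wnt+ replicate 3 (0.0575, 0.149, 0.147). The splicing factor genes SRSF5 and TRA2B lost theirs without the same 3 libraries (0.0827 and 0.146, 0.0547 and 0.153, 0.129 and 0.168) and without dual-aptamer Wnt- replicate 3 (0.0596 and 0.128). WDR43, MYBBP1A, SRSF5 and TRA2B lost the call in 9, 9, 8 and 9 refits in all, and with the replicate block (0.0853, 0.0613, 0.0718 and 0.0938) or a fit of the 6 libraries compared (0.165, 0.151, 0.156 and 0.187). TRA2B (-0.20) also lost it with the length trend removed (-0.14, 0.141) and with trends on length, span and GC removed (-0.13, 0.0941). NFKB2 lost its call without dual-aptamer Wnt- replicates 1 and 2 (0.0818, 0.0528) or Wnt+ replicates 1 and 3 (0.087, 0.115). The p53 target AEN (-0.20), a nuclease gene, kept its call only without individual-aptamer Wnt+ replicate 2 or dual-aptamer Wnt+ replicate 2, with 0.0542 to 0.182 in the other 10 refits. Without dual-aptamer Wnt- replicate 2 the p53 list gave 0.301. Higher lists were epithelial markers (2 of 9 rose, 3 over the list alone; median 0.32, 0.00621), with KRT19 rising by 0.41, and ribosomal proteins (0 of 46 called; 0.13, 3.39e-07) and oxidative phosphorylation (0 of 29 called; 0.13, 4.87e-05), none called over the list alone. Their adjusted p were 0.0977, 0.605 and 0.605 with an estimated correlation. Medians of the last 2 lists were 0.06 and 0.06 without dual-aptamer Wnt- replicate 3 and 0.08 and 0.08 without dual-aptamer Wnt+ replicate 3, and the ribosomal protein median was 0.20 without replicate 2 of either dual-aptamer group. Without replicate 2 of both groups together, the 2 medians were 0.27 and 0.25. KRT18, the other epithelial gene called, lost its call without dual-aptamer Wnt- replicates 1 and 3 (0.115, 0.138), dual-aptamer Wnt+ replicates 1 and 3 (0.129, 0.132) or individual-aptamer Wnt- replicate 2 (0.0504). Counting the other settings too, its call held in 16 of 23 alternatives.

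The O-GlcNAc and hexosamine list was lower at an adjusted p = 0.0495 (0 of 11 called, 1 higher and 3 lower over the list alone; adjusted p = 0.197 with an estimated correlation). That call was lost without dual-aptamer Wnt- replicate 2 (0.0774) or 3 (0.0849), dual-aptamer Wnt+ replicate 3 (0.132), individual-aptamer Wnt- replicate 1 (0.0576), 2 (0.0522) or 3 (0.0529), or individual-aptamer Wnt+ replicate 1 (0.055) or 2 (0.0501). It was also lost with the replicate block (0.0665), library size alone (0.0683), the length trend removed (0.0711), trends on length, span and GC removed (0.17) and both dual replicate 2 libraries left out (0.0919), and held in 5 of 19 alternatives. The 20 lists that did not pass had adjusted p between 0.186 and 0.999 and held 15 called members, 3 of them hypoxia targets (2 higher, STC1 among them, and ANKRD37 lower; 4 and 2 over the list alone; adjusted p = 0.347). Glycolysis genes (0.186) also held 3, with SLC2A3 and ENO2 higher and HK2 lower. ENO2 lost its call without dual-aptamer Wnt- replicate 1 (0.0718) or Wnt+ replicate 1 (0.0976), and HK2 without dual-aptamer Wnt- replicate 1 (0.12) or 3 (0.11) or dual-aptamer Wnt+ replicate 1 (0.094) or 3 (0.129). Wnt components had 2 higher of 32 (4 over the list alone; 0.999). The median, mean and test did not share a sign for Wnt components, endoplasmic reticulum chaperones and leukocyte markers.

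**Figure D2:**
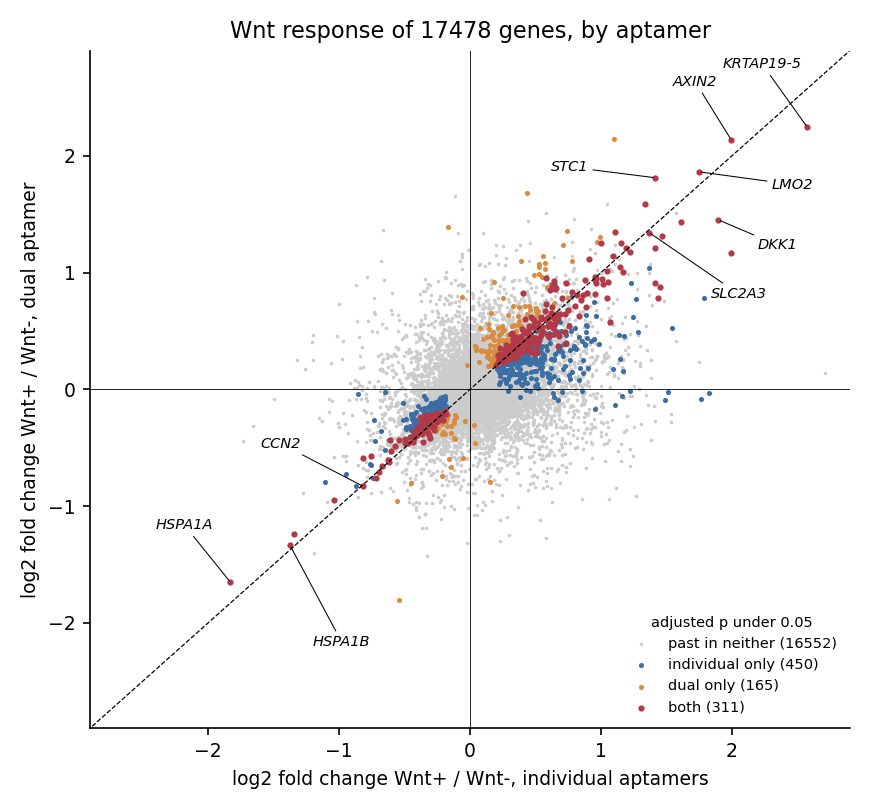
Log2 fold change of Wnt+ over Wnt- for 17478 genes with the individual aptamers (x axis) and the dual aptamer (y axis), coloured by edgeR call; the dashed line marks equal changes. The 311 genes called with both aptamers lie on the same side of 0 on both axes.

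Both Wnt responses were measured in separate libraries and shared none, but their calls came from 1 fit with a shared estimate of the spread. Leaving out dual-aptamer Wnt+ replicate 2 moved even the individual-aptamer count, from 761 to 1140. The 2 sets of calls were thus not independent, and the overlap of independent lists given below is only a reference. Of genes called with either aptamer, 214 were higher with both, where independent lists would share 8.77, and 97 were lower with both, against 2.4; 0 were called in opposite directions. Of 926 genes called with at least 1 aptamer, 903 had the same sign with both. Across all tested genes the fold changes correlated with r = 0.432 and rho = 0.495, a description over genes, which are not independent replicates. The 450 genes called with the individual aptamers alone and the 165 called with the dual aptamer alone are not thereby shown to differ. The test of the difference itself, the interaction of aptamer and medium, called 0 genes with edgeR (lowest adjusted p = 1; 625 genes with an unadjusted p under 0.05, against 874 by chance), 0 with DESeq2 and 0 with limma voom. For AXIN2 the difference of the responses was 0.14 (95% interval -0.11 to 0.40), for CTNNB1 0.01 (-0.14 to 0.16), and the median interval half-width over genes was 0.22. No list passed either. The lowest adjusted p was 0.0599, for ribosome biogenesis and for E2F genes, and 0.757 was the lowest with an estimated correlation. The median, mean and test did not share a sign for hypoxia and NF-kappaB targets, fatty acid synthesis, Wnt components, abundant non-coding RNAs, epithelial markers and the YAP, TGF-beta and BMP list. Lists did pass without individual-aptamer Wnt- replicate 3 (8), dual-aptamer Wnt- replicate 2 (10), individual-aptamer Wnt+ replicate 3 (3), or dual-aptamer Wnt+ replicate 2 (6) or 3 (1). By the rotation test fry, which does not compare a list with other genes, 0 lists passed for the interaction, 0 between aptamers in Wnt- and 0 in Wnt+, and 13 and 14 passed in the Wnt responses with the individual and dual aptamers.

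**Figure D3:**
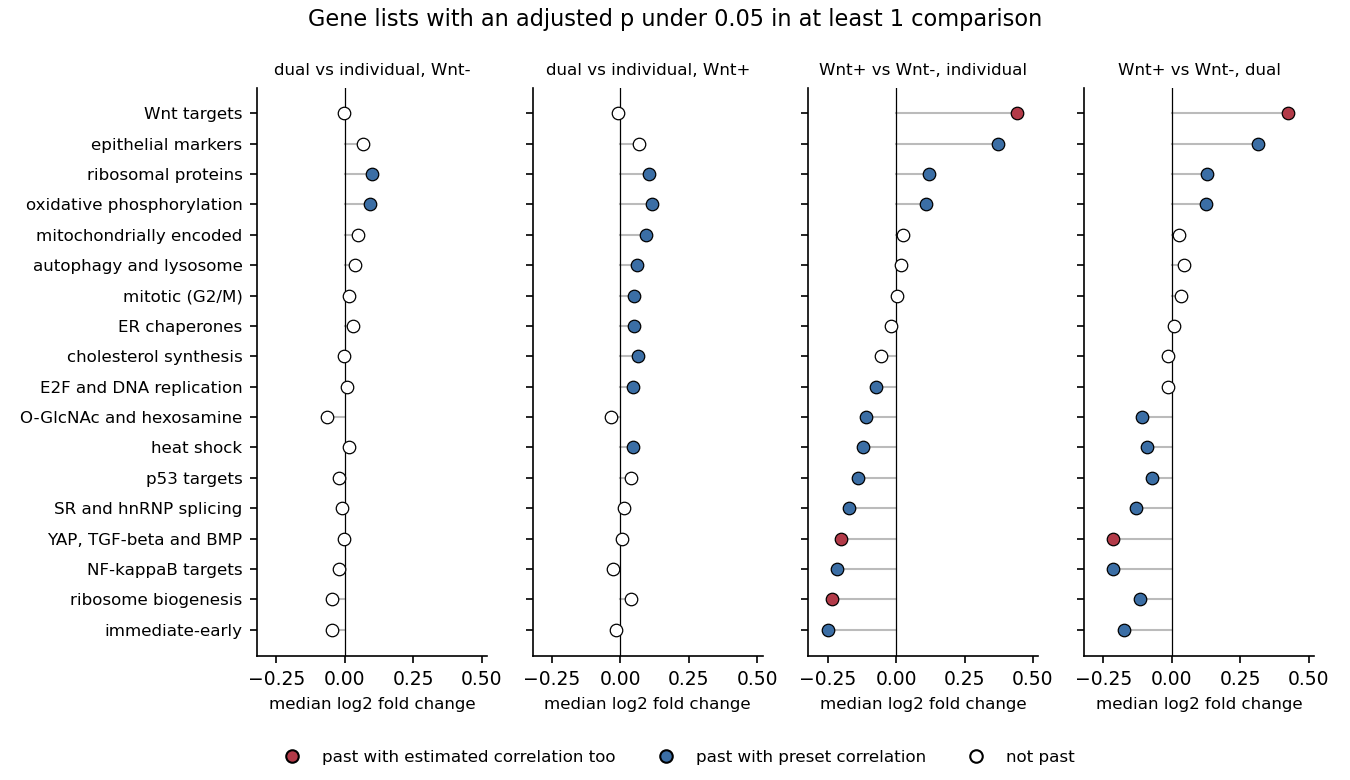
Median log2 fold change (x axis) of 18 gene lists (y axis) in the comparisons of aptamers and of media, filled where the adjusted p of camera is under 0.05 and red where it is also under 0.05 with an estimated correlation. Wnt targets have medians of 0.44 and 0.43 in the comparisons of media.

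The dual aptamer was compared with the individual aptamers in Wnt- to ask whether it changed expression without added Wnt. AXIN2 differed by 0.01 (95% interval -0.19 to 0.21, adjusted p = 0.987), CTNNB1 by 0.06 (-0.04 to 0.16, 0.761), OGT by -0.06 (SE 0.07, 0.823) and OGA by -0.06 (SE 0.06, 0.789). The Wnt target list had 0 of 25 members called, 0 adjusted over the list alone, and 12 of 25 positive (adjusted p = 0.903), with a median just below 0 and a positive mean. Ribosomal protein genes were higher in 45 of 46 (median 0.10, adjusted p = 5.14e-07), for example RPS23 at 0.17 (SE 0.07, adjusted p = 0.73), and oxidative phosphorylation genes in 28 of 29 (0.09, 9.41e-05), for example NDUFA4 at 0.15 (SE 0.06, 0.73). In both lists 0 members were called, over all genes or over the list alone, and both had an adjusted p = 0.975 with an estimated correlation.

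Over all genes, edgeR called 0 of 17478 in Wnt-, DESeq2 called 1 and limma voom 0. The lowest adjusted p was 0.319, and 1119 genes had an unadjusted p under 0.05, against 874 by chance; the median interval half-width was 0.157 on the log2 scale. The other 30 lists did not pass (0.126 to 0.965), the O-GlcNAc and hexosamine list among them (0.750). Adjusted over the list alone they held 1 higher gene, the hypoxia target EGLN3 (0.37, SE 0.09; adjusted p = 0.73 over all genes), chosen after its values were seen. Lists whose median, mean and test did not share a sign were Wnt, interferon, NF-kappaB, hypoxia and E2F targets, the YAP, TGF-beta and BMP list, cholesterol synthesis and leukocyte markers. The size of both list shifts rested on single libraries. The ribosomal protein list did not pass without individual-aptamer Wnt- replicate 3 (median 0.04, 0.2) or dual-aptamer Wnt- replicate 2 (0.01, 0.55), and its median was 0.16 without dual-aptamer Wnt- replicate 3. The oxidative phosphorylation list did not pass without the former (0.03, 0.483) or the latter (0.03, 0.352) of the first 2 libraries, and its median was 0.15 without dual-aptamer Wnt- replicate 3.

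In Wnt+, the same comparison asked whether the dual aptamer altered expression while the pathway was stimulated. AXIN2 was at 37.7 ± 2.17 CPM with the individual aptamers and 41.8 ± 2.97 CPM with the dual aptamer (SD, n = 3), a log2 difference of 0.15 (95% interval -0.01 to 0.31, adjusted p = 0.847). CTNNB1 differed by 0.07 (-0.03 to 0.17), OGT by -0.08 and OGA by -0.07, each with an adjusted p = 0.847. Wnt targets again had 12 of 25 positive, 0 called and 0 over the list alone (adjusted p = 0.953), with a median and test below 0 and a positive mean. Ribosomal protein genes were higher in 46 of 46 (median 0.10, adjusted p = 2.2e-10) and oxidative phosphorylation genes in 28 of 29 (0.11, 1.64e-08), with NDUFA1 at 0.19, not past the threshold alone (0.847). With an estimated correlation these lists had an adjusted p = 0.638 and adjusted p = 0.55. Their medians were 0.17 and 0.18 without dual-aptamer Wnt+ replicate 2 and 0.06 and 0.07 without dual-aptamer Wnt+ replicate 3.

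A further 7 lists were higher by small amounts in Wnt+: mitochondrially encoded genes (median 0.09, adjusted p = 6.09e-04), mitotic genes (0.05, 7.75e-04), cholesterol synthesis (0.06, 0.00353), E2F and DNA replication genes (0.05, 0.00353), endoplasmic reticulum chaperones (0.05, 0.00454), autophagy and lysosome genes (0.06, 0.0317) and heat shock genes (0.05, 0.0331). With an estimated correlation none of these 7 passed, with adjusted p of 0.533, 0.533, 0.533, 0.537, 0.537, 0.533 and 0.762. Members called numbered 0 over all genes and 0 over the list alone. CDK1 (0.13), INSIG1 (0.16) and the secreted chaperone gene MANF (0.15) were among them, all with an adjusted p = 0.847. Removing trends on length, span and GC ended all 7 calls: mitochondrially encoded genes (median 0.02, 0.55), heat shock (0.01, 0.34), chaperones (0.02, 0.131), lysosome (0.04, 0.103), mitotic (0.03, 0.0705), cholesterol (0.03, 0.0614) and E2F genes (0.04, 0.0614). The ribosomal protein (0.06) and oxidative phosphorylation (0.09) lists passed under it. Scaling by library size alone ended the heat shock (0.0716) and lysosome (0.0658) calls, with medians of 0.03 and 0.04. It also lowered the chaperone, E2F and mitotic medians to 0.03 each, and these lists still passed. Removing the length trend alone left the heat shock and lysosome medians nearly as they were (0.04 and 0.06). Their adjusted p then lay above the threshold (0.0782 and 0.0503). Without individual-aptamer Wnt+ replicate 1, 4 lists passed, and heat shock (0.369), cholesterol (0.151), E2F (0.0927), mitotic (0.0927) and lysosome (0.278) lists did not. Other single libraries that ended calls were individual-aptamer Wnt+ replicate 2 (chaperones, 0.0563) and 3 (lysosome, 0.111), and dual-aptamer Wnt+ replicate 1 (chaperones 0.0628, heat shock 0.144, lysosome 0.0853), 2 (cholesterol 0.159, lysosome 0.144) and 3 (heat shock 0.172). Heat shock medians were 0.02, 0.03 and 0.03 without individual-aptamer Wnt+ replicate 1 and dual-aptamer Wnt+ replicates 1 and 3, and the chaperone median was 0.03 without dual-aptamer Wnt+ replicate 1. Without dual-aptamer Wnt+ replicate 2, medians were 0.19 for mitochondrially encoded genes, 0.08 for chaperones and 0.07 for heat shock genes, and without individual-aptamer Wnt+ replicate 3 that of mitotic genes was 0.07.

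Over all genes in Wnt+, edgeR called 0, DESeq2 1 and limma voom 0, with a lowest adjusted p of 0.132 and 831 genes with an unadjusted p under 0.05, against 874 by chance. The other 23 lists did not pass (0.129 to 0.953), including the O-GlcNAc and hexosamine list (0.929). Adjusted over the list alone they held 1 lower gene, the abundant non-coding RNA NEAT1 (-0.30, SE 0.09; adjusted p = 0.847 over all genes), chosen after its values were seen. The median, mean and test did not share a sign for Wnt, ATF4 and hypoxia targets, the YAP, TGF-beta and BMP list, abundant non-coding RNAs and fibroblast markers. Between the media, the aptamer effects correlated across genes with r = 0.147 (rho = 0.228, covariance 0.00724), and r was 0.0301, 0.04 and 0.0364 without individual-aptamer Wnt+ replicate 2, dual-aptamer Wnt- replicate 2 and dual-aptamer Wnt+ replicate 3, and 0.229 without dual-aptamer Wnt+ replicate 2.

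The ribosomal protein and oxidative phosphorylation lists moved with a measure, based on transcript length, that also varied between replicates. Members of these lists were not left out of the measure, so part of the shared movement may be built in. The mean log2 deviation of short transcripts (exonic length up to 3844 bp) minus that of long ones (from 8433 bp) was -0.0888 ± 0.0593 with the individual aptamers and -0.00227 ± 0.161 with the dual aptamer in Wnt-, and -0.0135 ± 0.0676 and 0.104 ± 0.162 in Wnt+ (SD, n = 3). Ribosomal protein genes deviated by -0.105 ± 0.0986, -0.0129 ± 0.142, 0.00751 ± 0.0545 and 0.11 ± 0.112 in the same groups (SD, n = 3). Within groups, 1 component of 6842 well-expressed genes held 61.5% of the variance and correlated with exonic length across genes (rho = 0.613). Dual-aptamer Wnt- replicate 2 (-9.19) and dual-aptamer Wnt+ replicate 2 (10.1) lay at its ends, with the other libraries between -6.11 and 6.34.

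**Figure D4:**
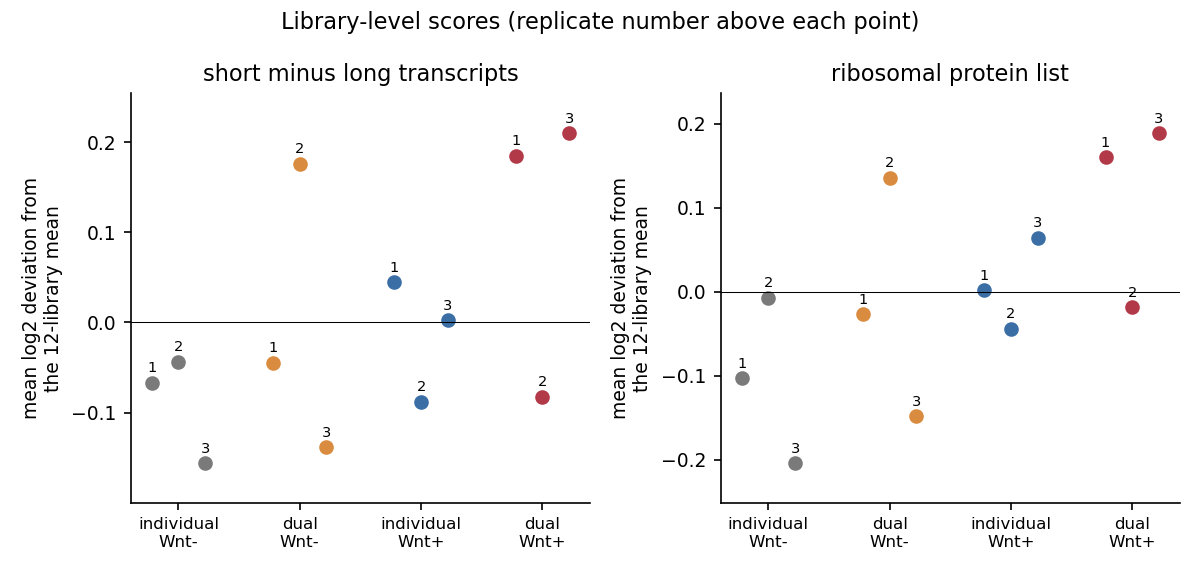
Mean log2 deviation from the mean of 12 libraries of short minus long transcripts (left) and of ribosomal protein genes (right), 1 point per library with its replicate number. Dual-aptamer Wnt- replicate 2 is at 0.176 and the other libraries of its group are at -0.0448 and -0.138 in the left panel.

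Without replicate 2 of both dual-aptamer groups, an alternative chosen after seeing the data, edgeR called 1022 genes between aptamers in Wnt+ (309 higher, 713 lower), 1 in Wnt- and 6 for the interaction, all 6 lower: EYA4, ITPR2, APC, CRTC3, FOXO1 and CRIM1, chosen after their values were seen. The Wnt response then had 2109 genes with the individual aptamers (1043 higher, 1066 lower) and 3642 with the dual aptamer (1661 higher, 1981 lower), so that lower calls outnumbered higher ones with either. With the transcript length trend removed as well, 0 genes were called for the interaction, so the 6 named genes lost their calls. Between aptamers in Wnt+, 481 calls were left.

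A single gene was called between aptamers in the authors' deposited tables and was chosen after its values were seen. ENSG00000259410, annotated as a long non-coding RNA on chromosome 15 from 67832725 to 67873866 on the plus strand, was at 12.8 ± 0.309 CPM with the individual aptamers and 6.68 ± 0.782 CPM with the dual aptamer in Wnt-, and at 11.7 ± 1.73 and 5.63 ± 1.63 CPM in Wnt+ (SD, n = 3). The authors' deposited tables give log2 fold changes of -0.95 (adjusted p = 8.93e-04) and -1.04 (adjusted p = 5.2e-05), and the next lowest adjusted p in these tables was 1 and 0.153. With edgeR the values were -0.94 (95% interval -1.28 to -0.61, adjusted p = 0.319) and -1.04 (-1.38 to -0.70, adjusted p = 0.132). Averaged over both media, a contrast added after seeing the data, it was the 1 gene called by edgeR (-0.99, SE 0.11, adjusted p = 0.0025). In that contrast 1713 genes had an unadjusted p under 0.05 with edgeR, against 874 by chance. Genes are not independent, and the cause of this excess was not tested. All 6 dual-aptamer libraries, up to 7.41 CPM, lay below all individual-aptamer libraries, from 9.96 CPM. Without dual-aptamer Wnt+ replicate 2 edgeR called 1 gene in each medium, and 3 averaged over both. Across genes the authors' deposited fold changes correlated with those of edgeR at r = 0.9997 and 0.9998.

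**Figure D5:**
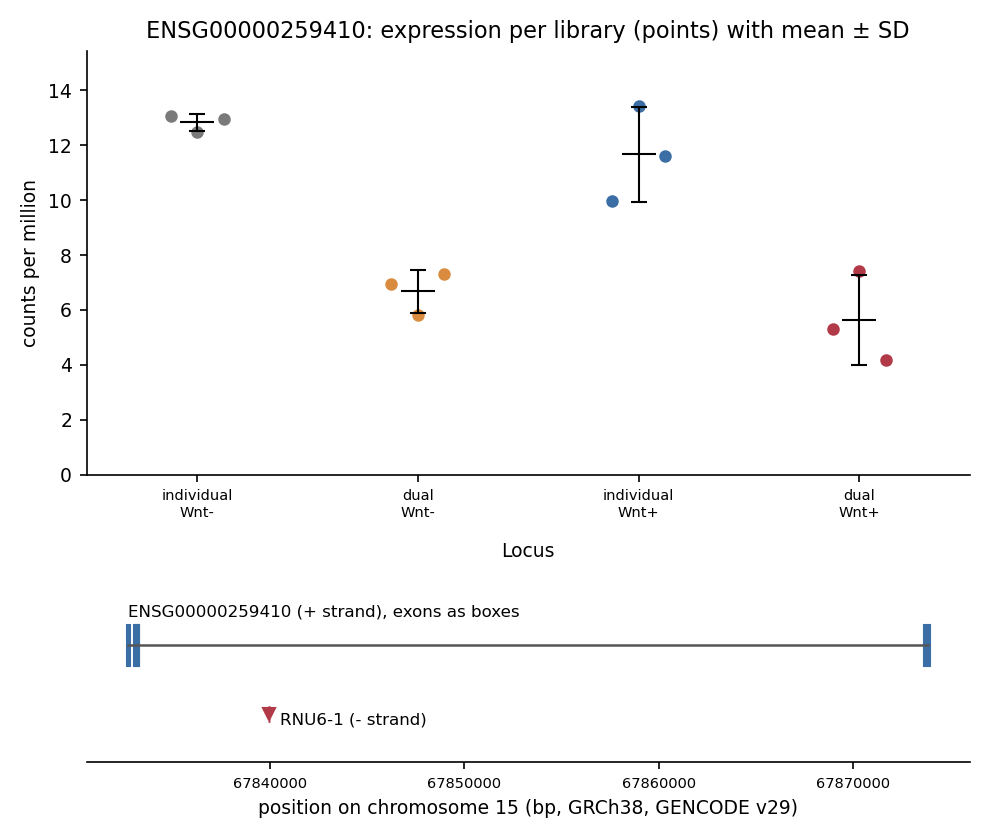
CPM of ENSG00000259410 in each library with mean and SD (top), and its exons on chromosome 15 with the U6 gene RNU6-1 on the opposite strand (bottom). All dual-aptamer libraries lie at or below 7.41 and all individual-aptamer libraries at or above 9.96 CPM.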

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

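No test in this part was chosen after the result was seen. ANKRD37, a hypoxia-inducible gene in the hypoxia list, moved in opposite directions with the dual aptamer in the 2 media: 106 named genes and 32 lists were checked for this, and it was the 1 result found. In Wnt- its level was 1.46, 0.984 and 1.04 CPM with the individual aptamers and 1.74, 1.54 and 1.92 CPM with the dual aptamer. In Wnt+ it was 1.35, 1.36 and 1.13 CPM with the individual and 1.02, 0.969 and 1.00 CPM with the dual aptamer. All 3 dual-aptamer libraries therefore lay above the individual-aptamer libraries in Wnt- and below them in Wnt+. Within 1 medium alone, chance separates 3 libraries from 3 in either direction for 10% of genes. That is not the rate for the pattern over both media. Most genes checked were named from these same data. ANKRD37 was named for its fall in Wnt+ with the dual aptamer (-0.79), a choice that itself favours this pattern. The difference between the aptamer effects was -0.95 on the log2 scale (SE 0.30), and in the interaction test over all genes its adjusted p = 1, so it did not pass. The aptamer effects themselves were 0.59 in Wnt- (adjusted p = 0.73) and -0.36 in Wnt+ (adjusted p = 0.847). The counts behind these levels were low, 22 to 44 per library. No explanation was tested for this gene.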

How the results depend on the processing

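Trend removal and leaving out replicate 2 of both dual-aptamer groups were chosen after seeing the data; the mean effect over both media was added likewise. Of the alternatives other than leaving out 1 library, the count of called genes stayed within 1.5 times in 9 of 13 for the aptamer effect in Wnt-, 10 of 13 in Wnt+, 8 of 13 for the Wnt response with the individual and 6 of 13 with the dual aptamer, 10 of 12 for the interaction and 8 of 10 for the mean effect. For the aptamer effect in Wnt- and Wnt+ and the interaction the main count was 0, so only a count of 0 was within this limit. The stricter thresholds of 0.01 and 1.5-fold could give only 0 there, so these agreements were fixed in advance. No called named gene reversed, but 21 of 47 and 16 of 33 lost the call in at least 1 alternative. In the fit of the 6 libraries compared these included KRT19 (0.0602) and DUSP5 (0.0634) with the dual aptamer. DESeq2 called 1 gene in Wnt- and 1 in Wnt+. With no filter on low counts the counts were 104 in Wnt- (42 higher, 62 lower), 35 in Wnt+ (3 and 32), 1407 and 882 for the Wnt responses, 44 for the interaction and 282 for the mean effect; the cause was not tested. Fitting only the 6 libraries compared gave 1 in Wnt-, and 1861 and 114 for the Wnt responses with the individual and dual aptamers; beyond the fewer libraries in the fit, the cause was not tested. Without replicate 2 of both dual-aptamer groups the counts were 1 in Wnt-, 1022 in Wnt+, 2109 and 3642 for the Wnt responses, 6 for the interaction and 168 for the mean effect. The replicate number as a block gave 304 for the Wnt response with the dual aptamer, and removing trends on length, span and GC gave 857; the cause was not tested. An adjusted p under 0.01 left 218 and 146 genes and a minimum of 1.5-fold left 192 and 128, by construction of the stricter thresholds.

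Within 1.5 times, DESeq2 called 997 and 611 genes in the Wnt responses (708 and 437 shared), limma voom 746 and 444, RLE size factors 765 and 442, library size alone 733 and 493, and removal of the length trend 1040 and 658. DESeq2's split with the individual aptamers was 461 higher and 536 lower. Leaving out 1 library gave 0 to 1 in Wnt-, 0 to 1 in Wnt+, 243 to 1140 and 162 to 1313 for the Wnt responses, 0 to 0 for the interaction and 1 to 3 for the mean effect. The count of 162 was without dual-aptamer Wnt+ replicate 1; 174, 219, 206 and 1313 were without dual-aptamer Wnt- replicates 1 and 3 and Wnt+ replicates 3 and 2. Those of 243, 316, 451, 276 and 262 were without individual-aptamer Wnt- replicates 1, 2 and 3 and Wnt+ replicates 1 and 3. The single calls in Wnt- and Wnt+ and the 3 for the mean effect were without dual-aptamer Wnt+ replicate 2.

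Of lists, an estimated correlation left 0 in Wnt-, 0 in Wnt+, 3 and 2 for the Wnt responses and 0 of 5 for the mean effect, because the set's variance then grows with the correlation. Without both dual replicate 2 libraries 5 passed in Wnt-, 9 for the interaction and 3 for the mean effect. The 5 in Wnt- did not include ribosomal proteins (median 0.02, camera adjusted p = 0.328) or oxidative phosphorylation (0.03, 0.225). Removing length, span and GC trends left 2 in Wnt+. For the mean effect, RLE size factors, the replicate block, library size alone and the length trend removed each left 3; the cause was not tested. Leaving out 1 library gave 2 to 4 in Wnt- (4 without dual-aptamer Wnt- replicate 2), 4 to 10 in Wnt+ (4 without individual-aptamer Wnt+ replicate 1), 13 to 17 and 11 to 13 for the Wnt responses, 0 to 10 for the interaction and 3 to 8 for the mean effect. The correlation of the aptamer effects (0.147) was 0.0789 to 0.198 over other alternatives and 0.0301 to 0.229 without 1 library. The authors' tables held 1 gene each at 0.01 as well.

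Values that changed sign were all uncalled, and the cause was not tested. Most lay near 0, but the interaction of ENSG00000259410 ranged from -0.45 to 0.079 over all alternatives. AXIN2 between aptamers in Wnt- was -0.011 with no filter, -0.010 without both dual replicate 2 libraries, and -0.0537 to 0.0764 without 1 library. CTNNB1 in the Wnt response was 0.039 (individual) and 0.014 (dual) with all trends removed and 0.0012 (dual) with the length trend removed. For the interaction, CTNNB1 was -0.012 with library size alone, -0.025 with all trends removed and -0.0075 to 0.037 without 1 library. OGT was -0.092 to 0.041 without 1 library, and OGA 0.0072 with no filter and -0.054 to 0.032 without 1 library. ENSG00000259410 was 0.023 with all trends removed and -0.352 to 0.079 without 1 library. The median interval half-width of the aptamer contrasts was 0.157 in Wnt- and 0.156 in Wnt+ on the log2 scale; no test varied depth.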

Other observations

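The tests on long genes, on ENSG00000259410, on calls without a pair of libraries, on lists lower in Wnt+ and on other splits were all chosen after the results were seen. Genes spanning more than 500 kb (364 genes, chosen after their values were seen) were lowest in the 3 individual-aptamer Wnt- libraries, with mean log2 CPM of 1.91, 2.38 and 2.28. The means were 2.44 to 2.69 with the dual aptamer in Wnt-, 2.41 to 2.63 with the individual aptamers in Wnt+ and 2.47 to 2.66 with the dual aptamer in Wnt+. Their median log2 fold change was 0.24 between aptamers in Wnt- (83.8% positive) and -0.08 in Wnt+ (36.3%). For the Wnt response it was 0.32 with the individual aptamers (88.7% positive, 26 called higher and 1 lower) and -0.03 with the dual aptamer (43.1%, 4 higher and 1 lower). The difference between these responses had a median of -0.31, with 8.79% positive and 0 genes called by edgeR, DESeq2 or limma voom over all genes, where 625 had an unadjusted p under 0.05. Individual-aptamer Wnt- replicate 1 was the lowest of these libraries, and no explanation was tested.

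ENSG00000259410 was lower with the dual aptamer by 0.99 on the log2 scale on average over both media (-0.99, SE 0.11). A single aberrant library is argued against, since the highest adjusted p over 12 refits, each without 1 library, was 0.0187. A change of the whole locus is argued against by the 12 tested genes within 500 kb, whose median was 0.0273 (range -0.637 to 0.162), with 0 past the threshold. What stays open is a technical origin in the plasmids. The sources used here do not say whether the plasmids carry a U6 promoter. If they do, its reads could be counted here and differ between plasmid mixes. The U6 gene RNU6-1 (67839939 to 67840045, minus strand) lies inside the span but overlaps none of its exons and had 0 counts in the 12 libraries. Sequence beside it lies between exons too, as the nearest ones end at 67833257 and start at 67873697. Counting by exon with this annotation would leave such reads out. The annotation used for the counting is not given, so counts per gene leave a plasmid origin undecided. A response of the gene to the dual aptamer was not tested apart from this and stays open.

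The calls between aptamers in Wnt+ that appeared without replicate 2 of both dual-aptamer groups (1022) were weighed next. Labels swapped between media are argued against by AXIN2, at 9.74 CPM in dual-aptamer Wnt- replicate 2. This lies within the Wnt- range of 8.64 to 10.4 and far from the Wnt+ range of 36.3 to 45.2. AXIN2 was not called between aptamers, so it cannot show labels swapped between aptamers within a medium, which stays open. A trend on transcript length as the whole cause is argued against by the 481 calls left without the pair after that trend was removed. Before the removal, lower calls had a median exonic length of 9989 bp, higher calls 2827 bp and genes not called 4254 bp. Only a fitted trend on exonic length was removed here, so any part the fit missed, or trends on span and GC, stay open. Smaller group size alone is argued against by the other 8 pairs, which gave at most 1 call. Also open is the choice of the pair, as this pair was the only 1 of 9 to give so many calls. It was picked because those libraries lay farthest apart, which lowers the spread and may raise the count.

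Immediate-early, YAP and TGF-beta, heat shock and ribosome biogenesis lists were lower in Wnt+ with both aptamers. A length trend is argued against by the highest adjusted p of the 8 list tests after its removal, 4.01e-08, and a single library by the highest over 12 refits, 0.00123. With an estimated correlation, 3 of the 8 tests passed. Conditioned medium against fresh medium cannot be told apart from Wnt3A, because no group received conditioned medium without Wnt3A, and the highest of the 8 list medians, -0.0908, would be met by either. Serum factors used up in conditioned medium, or fresh medium itself raising these genes in Wnt-, are therefore candidate explanations beside Wnt3A.

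Other splits of the same libraries were counted for each result, and each count below includes the real split itself. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In Wnt-, 10 of 10 splits called as many genes as the real one (0, highest other 0), and in Wnt+ 10 of 10 (0, highest other 615). For the Wnt response with the individual aptamers 1 of 10 did (761, highest other 0), and with the dual aptamer 2 of 10 (476, highest other 2909). The split with 2909 exchanged replicate 2 of both dual-aptamer groups, which points to a structure of the samples. For lists, 9 of 10 splits passed as many in Wnt- (2, highest other 13), 2 of 10 in Wnt+ (9, highest other 9), and 2 of 10 in each Wnt response (13 and 12, highest other 14 in both). For the interaction the real counts of genes and lists were 0, so that 25 of 25 splits gave as many by construction and say nothing about chance (highest other 3884 genes and 15 lists). The same holds for the 0 genes between aptamers in Wnt- and Wnt+. Splits for the interaction also mixed libraries of both media, so the difference between media could enter their highest counts. Chance is not excluded for the mean aptamer effect, where 3 of 40 gave as many genes (1, highest other 971) and 10 of 40 as many lists (5, highest other 14).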
